A study of Mus musculus with 11 samples.

How the data were processed

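Total RNA from mouse feeder cells, induced pluripotent stem cells (iPSC) grown on such feeder cells and iPSC grown without them was labelled as biotinylated cRNA and hybridized to Illumina BeadChip arrays, per the labels. The series holds 11 samples: 2 arrays of feeder cells, 3 of feeder-free iPSC, 3 of iPSC on feeder cells, and 3 in silico mixtures that the authors computed as 92% feeder-free signal plus 8% feeder signal. Per the labels, the feeder cells were embryonic fibroblasts of strain C57BL/6 expressing LIF (leukemia inhibitory factor), the growth protocol names mitomycin C-treated SNL76/7 cells, the feeder-free medium held 1000 units per ml of LIF and 15% serum, and iPSC on feeder cells were lifted off the feeder layer mechanically. The labels call the feeder arrays MSTO and use the same name in the descriptions of the on-feeder arrays, but do not say how MSTO and SNL76/7 relate; every feeder share, the mixtures and levels relative to feeder cells hold only as far as the feeder layer resembled the cells on the feeder arrays. The labels number the replicates but do not say whether they are separate cultures, so every p-value measures only the spread between these samples.

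The deposited table of non-normalized bead intensity gave 1 signal per probe and column, per the file headers. Beside each measured array it holds a deposited detection score, headed as a p-value, which rose with the signal on every array (Spearman correlations from 0.9961 to 0.9987) and was therefore read as 1 minus the detection p. Of 46632 entries, 5 carried no probe ID and were left out, which held 0.498% of the signal of feeder array 1. Per the submitters' processing notes limma was used, with a version and a role not given in the sources used here. A further table by the authors holds intensity values normalized between arrays; its feeder columns matched the non-normalized ones probe by probe (Pearson correlations of log2 values 0.9969 and 0.9973), while its other 9 columns did not (-0.0294 to -0.0265), so it was not used.

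The deposited feeder-free intensity columns were not single arrays. The first and second were identical on 100% of probes and equalled 91% of the mean of the feeder-free arrays plus 9% of the mean of the feeder arrays, and the third held 92% and 8%. Single feeder-free arrays were recovered from the deposited mixture columns, each of which is 92% of a feeder-free array plus 8% of the feeder mean. The recovered arrays gave back the pooled columns to within 0.0512 signal units (median difference 0.0119). Their Spearman correlations with their own detection scores were 0.9965, 0.9968 and 0.9978, against 0.9684, 0.9714 and 0.9691 for the pooled columns.

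Signals were background-corrected with limma 3.58.1 in R 4.3.3 (normexp on negative-control estimates from detection p-values, offset 16), quantile normalized between the 8 measured arrays and put on the log2 scale. Probes detected (score over 0.95) on every array of at least 1 group were kept, 18144 of 46627. Gene symbols came from the probe table supplied with the array, with Entrez IDs looked up in the RefSeq gene table: 29972 probes had a single symbol, 10 had several and 16645 were not listed with a gene. The brightest probe stood for each gene, which left 10058 genes. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the files and drew the figures.

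Depth on these arrays is signal over background. Between 13581 and 14574 probes were detected on the feeder arrays, 17307 to 18759 on the feeder-free arrays and 17630 to 19043 on the on-feeder arrays, with a median signal 2.56 to 3.2 times that of undetected probes. The number of arrays limits the precision.

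Group means were compared with lmFit and eBayes in a single fit over the 8 measured arrays (5 residual degrees of freedom, 6.76 prior), two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The in silico mixture was rebuilt from background-corrected signals of each recovered feeder-free array and the feeder mean, because its columns carry no detection score; the 3 rebuilt mixtures and the 3 on-feeder arrays were normalized and fitted on their own (4 residual degrees of freedom). The mixtures come from the same arrays as the other groups and are not independent of them. Where a group was not detected on any array, the fold is given as a lower bound, with "at least". The reference was then the mean over that group's arrays of a floored signal. On each array the floor was the lowest level among detected probes, and any signal under it was raised to it. Rebuilt mixtures have no detection score, so their floor combined the feeder-free and feeder floors in the shares of the mixture. The share of feeder signal in iPSC on feeder cells was the median, over feeder-specific probes, of on-feeder minus feeder-free signal divided by feeder minus feeder-free signal. These probes were detected on both feeder arrays at a score over 0.99, on no feeder-free array, and at least 8-fold brighter in feeder cells with the offset included; a wider set took the fold after the offset was subtracted. For a single gene the same ratio is called its feeder share.

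The comparisons, 23 gene lists and the rule for naming genes were chosen before the data were examined. So were the alternatives, save those said further on to have been chosen later. The lists held 482 entries, 427 of them on the array, and some genes stood in several lists. Lists were tested with camera at a preset correlation of 0.01, camera with an estimated correlation, and fry, each adjusted over the lists. Named in each comparison were the 10 largest rises and 10 largest falls (5 and 5 for feeder-free iPSC against feeder cells) among genes past the threshold whose arrays did not overlap and that were detected throughout the higher group, Ccl2, Lif, Pou5f1, Nanog, Sox2 and Klf4, and up to 6 members per list with the smallest adjusted p. Genes named outside the rule are said to be so.

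The steps were tested on simulated data. With 100 genes changed by each fold, the feeder-free against feeder cells step recovered 60% of the 1.5-fold and 99% of the 2-fold changes with 4 false calls. The on-feeder against feeder-free step recovered 90% and 100% with 12 false calls, and the step against the mixture 89% and 98% with 10. A list of 15 genes shifted 1.5-fold was called while 0 of 22 others were, and a true feeder share of 5% was read as 4.61% on average. The list simulation does not show how calls fare with an estimated correlation, which left 0, 1 and 0 of the 10, 7 and 4 real calls. Mixtures rebuilt from the arrays with a true share of 8% read 5.6% on average. The simulated share therefore does not give the bias on the arrays. Alternatives tried were no background correction, an offset of 50, median scaling, no filter, a detection score over 0.99, the mean over a gene's probes, a mean-variance trend, a replicate block, only the arrays compared, other mixture shares, other feeder-specific probes, and leaving out each array.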

Results

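Gene expression was measured in feeder cells (2 arrays), feeder-free mouse iPSC kept in added LIF (3 arrays) and iPSC grown on feeder cells (3 arrays), with 3 in silico mixtures of feeder-free and feeder signal as a further reference. Arrays of 1 group resembled each other closely across genes, with lowest Pearson correlations of 0.9948 for feeder cells, 0.9938 for feeder-free iPSC and 0.9918 for iPSC on feeder cells. The median SD of a gene within a group was 0.08, 0.12 and 0.13 log2 units in that order. Both kinds of iPSC culture lay near each other (0.9755 to 0.9852) and far from feeder cells (0.8063 at most).

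Feeder-free iPSC were set against feeder cells to define which transcripts belong to which cell. The pluripotency factor Pou5f1 was 135-fold higher in feeder-free iPSC (log2 fold change 7.08, SE 0.31, adjusted p = 6.41e-10; 3 and 2 arrays), Nanog at least 46.8-fold and Sox2 31-fold. Dnmt3l, a partner of DNA methyltransferases, stood at 8.22 on the log2 scale (SE 0.30), Chchd10 at 7.74 and Snurf at 7.64, and Snrpn was at least 113-fold and the germline gene Tex19.1 at least 131-fold higher; the order of these rises is not resolved at the low feeder signal. The largest falls were those of the growth factor Ptn at -7.67 (SE 0.15), the collagen crosslinker Lox at -6.81, Medag at -6.59, Hoxa5 at -6.22 and the collagen gene Col6a1 at -5.94. Klf4 differed far less, at 1.02 (SE 0.16, adjusted p = 8.78e-05), because feeder cells carried it too, at a mean log2 level of 8.01 against 9.03. Dnmt3l, Chchd10, Snurf, Pou5f1, Sox2 and Esrrb (named below) were each detected on 1 of the 2 feeder arrays, and the choice of array moves their folds: Pou5f1 was at 6.27 without feeder array 1 and 7.83 without feeder array 2.

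Most chemokines sat on the feeder side. Ccl2, the CC chemokine the series title names, was at least 2.46-fold lower in feeder-free iPSC than in feeder cells (log2 fold change -1.59, SE 0.16, adjusted p = 1.48e-06), and Lif, the factor that feeder cells were made to express, was lower at -1.35 (SE 0.10). The neutrophil chemokine Cxcl1 was at -4.41, Cxcl12 at -5.08, Ccl7 at -3.66 and Ccl9 at least 10.7-fold lower, while Cxcl16 was higher in iPSC at 2.56.

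Of 10058 genes, 8228 (81.8%) differed, 4104 higher and 4124 lower in feeder-free iPSC, among them 2186 and 2077 by at least 2-fold. Median scaling in place of quantile normalization moved the median of all genes from -0.01 to -0.39 and left 2797 higher and 5203 lower, so the balance of directions rests on the scaling. The arrays did not overlap for 8835 genes, where chance gives 20%.

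All 17 measured members of the core pluripotency list were higher in feeder-free iPSC (adjusted p = 7.61e-08 by camera), as were 14 of 16 in the list of naive pluripotency and LIF-responsive factors (adjusted p = 6.04e-05), including Esrrb at 6.75 and Tfcp2l1 at 5.63. The fibroblast and extracellular matrix list was lower (25 of 28 members, 3 higher; adjusted p = 7.61e-08), with Loxl1 at -5.73, Serpinf1 at -5.20 and Timp2 at -4.06. Lower too were the chemokine list (12 of 13, adjusted p = 0.00214) and the actin cytoskeleton list (12 of 16, adjusted p = 0.00853), with Cav1 at -4.62 and Ankrd1 at -3.26. Early lineage lists were higher: primitive endoderm (11 of 15, adjusted p = 0.00293; Sox17 at least 14.6-fold, Gata6 at least 20.3-fold), mesoderm and primitive streak (6 of 8, adjusted p = 0.0265; Lefty2 at least 81.9-fold), and epiblast priming and ectoderm (9 of 12, adjusted p = 0.0162; Krt8 at least 57.1-fold). The germline and two-cell-like list (11 of 13, adjusted p = 0.000857) and the glycolysis and hypoxia list (14 of 22, adjusted p = 0.0376; Hk2 at 2.75) were higher as well. Counts adjusted over the list alone were the same as these for the 10 lists called. The glycolysis call ended with median scaling (adjusted p = 0.0617) and the mesoderm call without the filter on dim probes (adjusted p = 0.0503). With an estimated correlation none of the 10 calls held (adjusted p from 0.107 to 0.38), while fry, which compares no list with other genes, called 19 of 23.

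The other 13 lists were not called by camera in this comparison. Adjusted p was 0.903 for JAK-STAT3 and LIF feedback targets (8 higher and 7 lower of 18; Socs2 at 4.24, Osmr at -2.51), trophoblast (4 and 5 of 10), BMP-SMAD targets (3 and 3 of 7), unfolded protein and amino acid stress (9 and 6 of 20), oxidative stress and metallothionein (6 and 7 of 15) and housekeeping (5 and 4 of 10). It was 0.608 for FGF-ERK feedback (7 and 4 of 12) and for WNT-beta-catenin targets (4 and 2 of 6), 0.618 for cholesterol synthesis (8 and 5 of 16), 0.927 for p53 targets (8 and 9 of 18) and 0.185 for hematopoietic and endothelial cells (5 and 2 of 7). The G2/M genes of the cell cycle (10 and 2 of 18) had an adjusted p of 0.111, and the interferon response (4 and 11 of 18) one of 0.118, with Psmb8 at least 9.36-fold higher and B2m at -2.64. Adjusted over the list alone, only the G2/M counts changed, to 9 and 2. Median, mean and test differed in sign for trophoblast, BMP-SMAD targets, oxidative stress and housekeeping.

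The main comparison asked what growth on feeder cells changes against feeder-free growth with added LIF. Amounts of LIF and serum were available for the feeder-free cultures only. Effects of medium or harvest therefore cannot be told apart from effects of feeder cells. Cxcl1 rose most, 33-fold (log2 fold change 5.04, SE 0.13, adjusted p = 7.99e-10; n = 3 and 3). Ccl2 rose at least 4.21-fold, from a signal detected on 0 of 3 feeder-free arrays to a mean log2 level of 7.07 (2.36, SE 0.14, adjusted p = 3.54e-07). Lif transcripts were 1.76-fold higher (0.82, SE 0.09, adjusted p = 5.93e-05). Pou5f1 (-0.16, SE 0.28, adjusted p = 0.722) and Nanog (0.20, SE 0.16, adjusted p = 0.401) showed no change past the test, and Sox2 (-0.33, SE 0.16, adjusted p = 0.178) passed it only without on-feeder replicate 2, at -0.50. The SE of Pou5f1 pools the feeder arrays, where its SD was 1.06, against 0.13 in feeder-free iPSC and 0.18 on feeder. Klf4 fell by 0.94 (SE 0.15, adjusted p = 0.00101), a fall seen by 2 of its 3 kept probes; the dimmest read 0.50 with an adjusted p of 0.176.

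Cxcl1 and Ccl2 were joined by other chemokines. Ccl7, a close relative of Ccl2, rose 6.01-fold (2.59, SE 0.12, adjusted p = 3.96e-08), Ccl9 at least 3.78-fold (2.24, SE 0.11) and the membrane-bound Cx3cl1 2.17-fold (1.12, SE 0.10), whereas Cxcl16 fell by 0.95 (SE 0.10, adjusted p = 3.61e-05) on the brighter of its 2 kept probes, the other at 0.03 (adjusted p = 0.888). In feeder cells Ccl2 stood at 6.30 and Cxcl1 at 10.46 on the log2 scale, below the levels in iPSC on feeder cells (7.07 and 11.09). Their feeder shares were 201% and 157%, against 43.1% for Ccl7, 30% for Ccl9 and 20% for Cx3cl1. Of 13 list members 7 rose and 1 fell, and 8 rose and 1 fell adjusted over the list alone (adjusted p = 0.000275 by camera; adjusted p = 0.0755 with an estimated correlation).

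**Figure D1:**
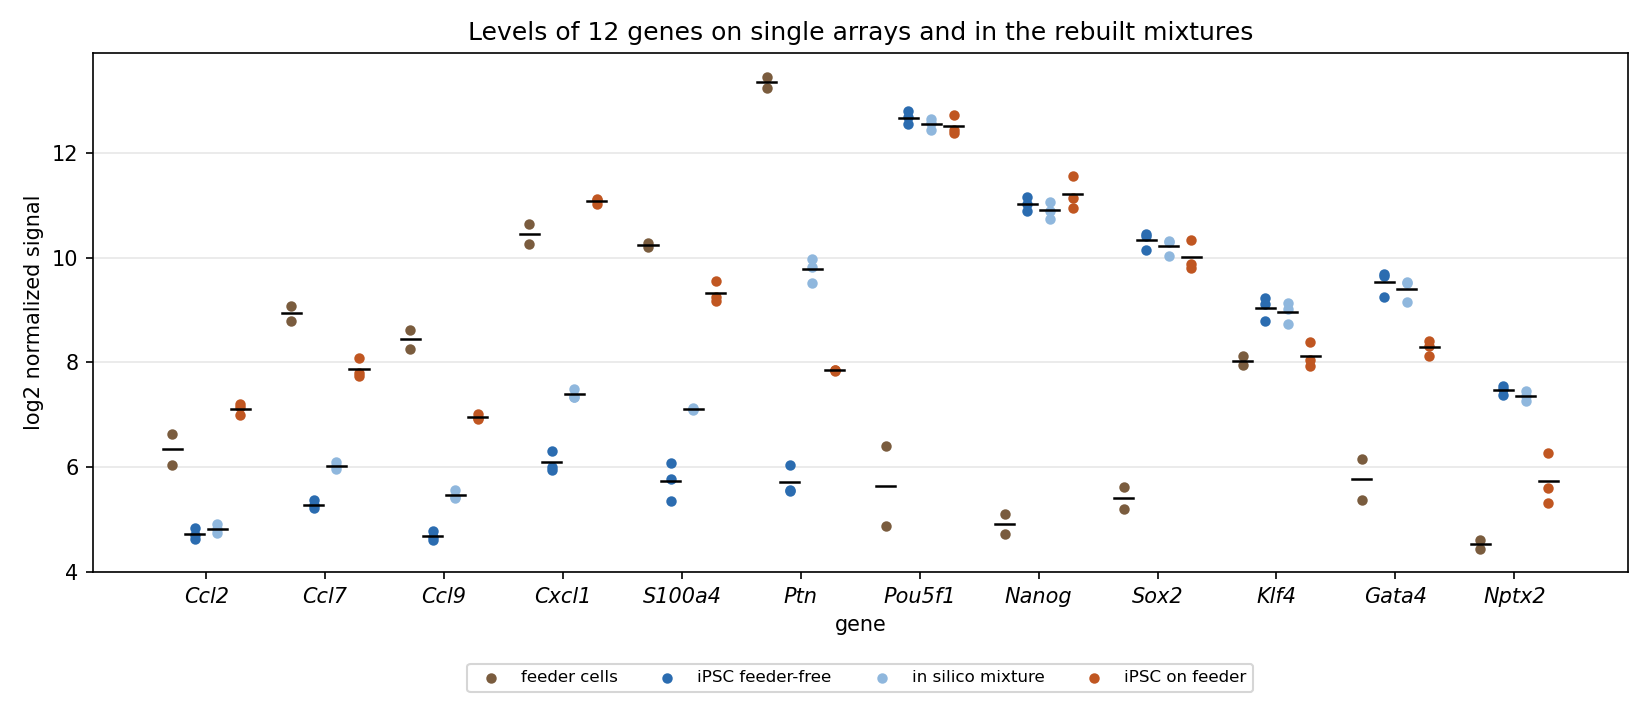
Log2 normalized signal of 12 genes on each array of feeder cells, feeder-free iPSC and iPSC on feeder cells and in the 3 rebuilt mixtures, with group means as black bars. Ccl2 and Cxcl1 on feeder lie above every other group, Ptn on feeder lies below the mixture, and Pou5f1 and Nanog lie level in all iPSC groups.

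The fibroblast and extracellular matrix list rose, and the largest single rises were also of genes higher in feeder cells. S100a4 rose 12.3-fold (log2 fold change 3.62, SE 0.16, adjusted p = 3.36e-08), the caveolar genes Cavin2 11.7-fold and Cav1 10.2-fold, the adhesion molecule Vcam1 10.3-fold and the hyaluronan receptor Cd44 8.54-fold. Feeder shares were 50.6% for S100a4, 19.7% for Cavin2, 39.2% for Cav1, 21% for Vcam1 and 41.4% for Cd44. Further rises were those of Medag (2.88, feeder share 6.65%), Col4a5 (2.84, 36.8%), Ecm1 (2.83, 67%) and Synpo (2.62, 45.2%). In the fibroblast and extracellular matrix list 21 of 28 members rose and 1 fell (23 and 1 adjusted over the list alone), with a median of 1.47 and adjusted p = 1.24e-22. It was the only list whose call held with an estimated correlation (adjusted p = 0.0106). The 21 risen members, which are all higher in feeder cells, had feeder shares from 4.46% (Lox) to 85.5% (Tnc) with a median of 18.9%. Col6a1 rose by 2.50 with a share of 7.73%, Serpinf1 by 2.31 with 11.1%, Timp2 by 1.99 with 18.9% and the matrix protein Tnc by 2.39 with 85.5%.

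The actin cytoskeleton and smooth muscle list moved the same way, with 6 of 16 higher and 1 lower (8 and 2 adjusted over the list alone; adjusted p = 0.00828, adjusted p = 0.145 with an estimated correlation). Ankrd1, a target of the YAP and TAZ coactivators, rose 5.05-fold with a feeder share of 47.4%, Anxa1 2.9-fold with 35.9% and Anxa2 1.99-fold, and Zyx rose by 0.57.

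Primitive endoderm, mesoderm and BMP-SMAD lists fell. In the primitive endoderm list 8 of 15 members were lower and 1 higher (9 and 1 adjusted over the list alone; median -0.36, adjusted p = 0.000501, adjusted p = 0.317 with an estimated correlation). Gata4, a driver of this lineage, fell by 1.26 (SE 0.18, adjusted p = 0.000588; n = 3 and 3), although the dimmer of its 2 kept probes read 0.09 with an adjusted p of 0.676. The follistatin gene Fst fell by 0.89, Foxa2 by 0.68, Amn by 0.66 and the basement-membrane collagen gene Col4a1 by 0.61, each with an SE from 0.10 to 0.15; Pdgfra rose by 0.62 on the brighter of its 2 kept probes, while the other read -0.17 (adjusted p = 0.275). The mesoderm and primitive streak list had 4 of 8 lower and 0 higher, the same adjusted over the list alone (adjusted p = 0.0204, adjusted p = 0.232 with an estimated correlation; not called without on-feeder replicate 3, adjusted p = 0.0609, without the filter on dim probes, adjusted p = 0.203, or with a detection score over 0.99, adjusted p = 0.184). Its Bmp4 fell by 0.82 and Hand1 by 0.81. Among BMP-SMAD targets, 3 of 7 fell and 0 rose, also adjusted over the list alone (adjusted p = 0.0116, adjusted p = 0.232 with an estimated correlation), namely Bmp4, the NOTCH and BMP target Hey1 at -0.80 and Bmper at -0.57. The other members, Id1 (-0.225), Id2 (-0.126), Id3 (-0.275) and Id4 (0.068), did not pass the test, and Bmp4 counts in the mesoderm list too.

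The largest single falls lay outside these lists. The gastrokine genes Gkn1 and Gkn2, normally expressed in stomach, were at -1.76 (SE 0.10, adjusted p = 1.76e-07) and -1.41, the synaptic pentraxin Nptx2 at -1.74 (SE 0.19), Pga5 at -1.44, Nxf7 at -1.40 and the water channel Aqp8 at -1.34. Eif4ebp2 (-1.27), Tcf23 (-1.20) and the endothelial cadherin Cdh5 (-1.19) completed, with Gata4, the 10 largest falls. Apart from Eif4ebp2 and Gata4, none of these was detected on a feeder array.

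Regulators of pluripotency moved in both directions. The list of naive pluripotency and LIF-responsive factors had 4 of 16 lower and 1 higher, the same adjusted over the list alone (median -0.26, adjusted p = 0.0119, adjusted p = 0.485 with an estimated correlation). The imprint regulator Zfp57 fell by 0.97 (SE 0.13, adjusted p = 0.000344) along with Klf4, while Gbx2, a STAT3 target, rose by 0.76 (SE 0.14, adjusted p = 0.00318). Of the core pluripotency list 1 of 17 rose and 4 fell (1 and 5 adjusted over the list alone; adjusted p = 0.495), with Utf1 at -0.51. Among JAK-STAT3 and LIF feedback targets 5 of 18 rose and 1 fell, the same adjusted over the list alone (adjusted p = 0.468): Ier3 rose 2.51-fold with a feeder share of 36.8%, the oncostatin M receptor gene Osmr by 0.80 with 15.6%, and Lif itself had a share of 49.2%.

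Signalling and stress lists mostly split. FGF-ERK feedback had 4 of 12 higher and 2 lower (5 and 3 adjusted over the list alone; adjusted p = 0.321), with Fosl1 at least 1.83-fold higher, Dusp5 at 0.66 and Dusp4 at -0.60. WNT-beta-catenin targets had 1 of 6 higher and 2 lower (1 and 3 adjusted over the list alone; adjusted p = 0.913), with Ccnd1 up 2-fold and Axin2 at -0.72. In the interferon response list 5 of 18 rose and 2 fell (5 and 3 adjusted over the list alone; adjusted p = 0.303): Ifi27 rose 4.87-fold with a feeder share of 64.4% and the class I genes B2m and H2-D1 rose by 1.22 and 0.86, while the immunoproteasome gene Psmb8 fell by 0.55. The unfolded protein and amino acid stress list had 4 of 20 higher and 0 lower (adjusted p = 0.285), with Chac1 at 0.66 and Vldlr at 0.71. Glycolysis and hypoxia had 2 of 22 higher and 2 lower (adjusted p = 0.994; Vegfa 0.63, Pdk1 -0.48). P53 targets had 2 of 18 higher and 2 lower (adjusted p = 0.964; Fas at least 1.55-fold higher, Trp53i11 -0.55), oxidative stress and metallothionein 1 of 15 and 1 (adjusted p = 0.385; Txnip 0.72), and housekeeping 1 of 10 and 1 (adjusted p = 0.913; Rplp0 0.61); in these 4 lists and the stress list the counts adjusted over the list alone were the same.

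Few members of the remaining lists passed the test. G2/M genes had 2 of 18 higher and 0 lower (0 and 0 adjusted over the list alone; adjusted p = 0.285), and cholesterol synthesis 0 of 16 higher and 1 lower (0 and 0; adjusted p = 0.468). Epiblast priming and ectoderm had 0 of 12 higher and 2 lower (0 and 2; adjusted p = 0.231), with Krt8 at -0.39. Trophoblast had 1 of 10 higher and 1 lower (2 and 1; adjusted p = 0.913), germline and two-cell-like 0 of 13 in either direction (0 and 0; adjusted p = 0.964), and hematopoietic and endothelial cells 1 of 7 higher and 2 lower (2 and 2; adjusted p = 0.62). Fry called 13 of the 23 lists, 9 upward and 4 downward. The list of naive pluripotency and LIF-responsive factors, called by camera, was not among them (adjusted p = 0.0537 by fry). For the 7 lists called by camera, the median, the mean and the test had the same sign; among the others JAK-STAT3, germline, glycolysis and housekeeping had a median or mean that differed in sign from the test.

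**Figure D2:**
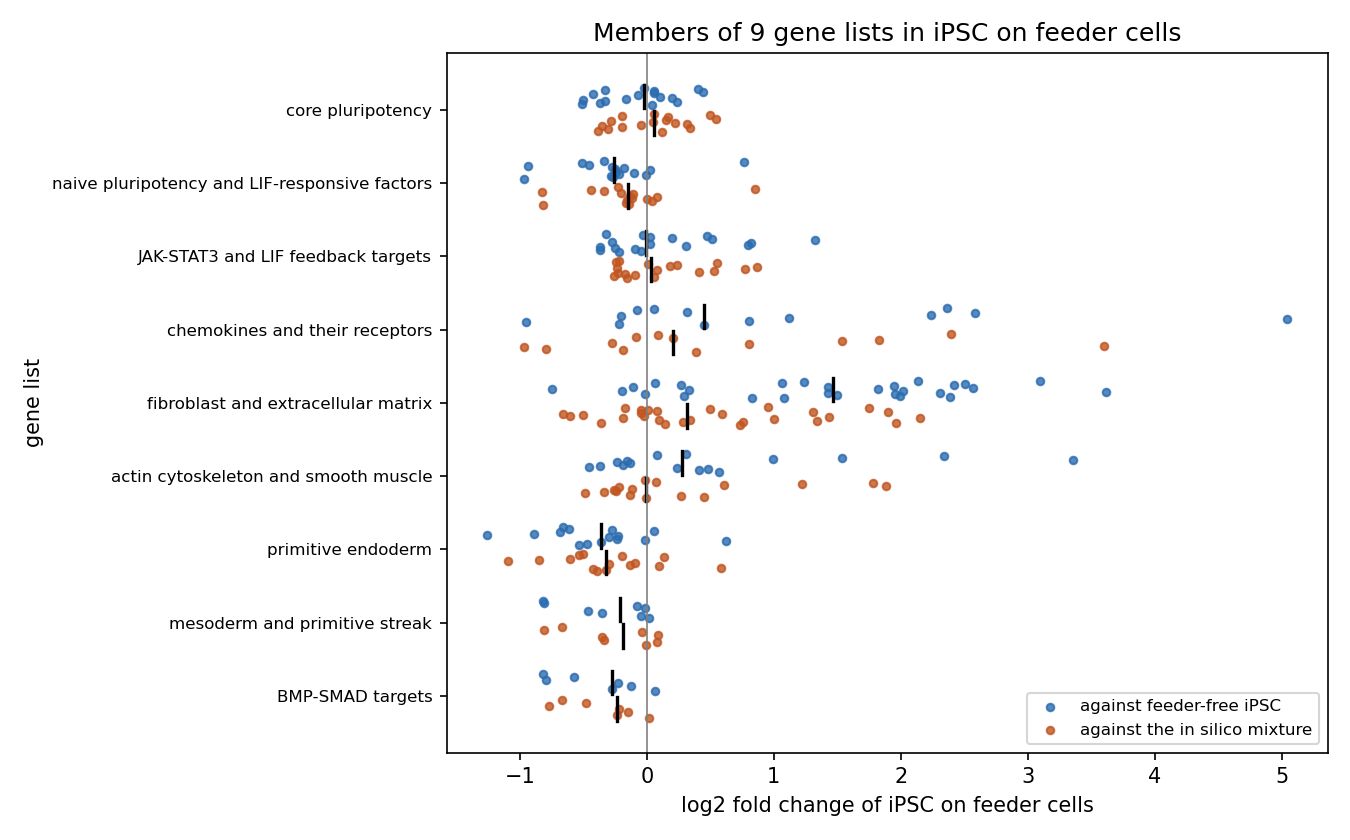
Log2 fold change of each measured member of 9 gene lists in iPSC on feeder cells, against feeder-free iPSC and against the rebuilt mixture, with list medians as black bars. The fibroblast median lies at 1.47 against feeder-free iPSC and 0.31 against the mixture, while that of primitive endoderm lies at -0.36 and -0.32.

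Across all genes 1827 (18.2%) differed, 992 higher and 835 lower, of which 171 and 24 by at least 2-fold; 3307 had an unadjusted p under the threshold. The arrays of both groups did not overlap for 3606 genes, where chance gives 10%. Besides Klf4, Gata4, Cxcl16 and Pdgfra, another kept probe did not pass the test for Anxa2 (0.21), Ccnd1 (0.51), Cd44 (0.14), Dusp4 (0.26, against a fall of the gene), Fas (0.06), Pdk1 (-0.30), Serpinf1 (0.23) and Vldlr (0.20 and 0.24). The count depended on single arrays: it was 1147 without feeder-free replicate 2, 1137 without feeder-free replicate 3, 1193 without on-feeder replicate 1 and 1165 without on-feeder replicate 3.

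Feeder-cell expression tracked these changes. Of the 992 risen genes 801 (80.7%) were higher in feeder cells than in feeder-free iPSC, against 407 expected from independent lists, and of the 835 fallen genes 587 (70.3%) were lower in feeder cells, against 341. Both comparisons share the feeder-free arrays, yet the correlation of the fold changes across genes, 0.475, exceeded the 0.0397 that the shared arrays alone gave in 100 simulated draws. Of the 992 risen genes 171 were also above feeder cells, against 388 expected from independent lists. The 8 of these that were at least 2-fold over feeder-free iPSC, chosen after their values were seen where the rule does not name them, were Ccl2, Cxcl1, the platelet chemokine gene Ppbp, the collagenase gene Mmp13, Mmp10, Serpinb2, Wwtr1 and Adam9. Of the 835 fallen genes 213 were below feeder cells too, against 348 expected. The counts of 171 and 213 come from comparisons that share the on-feeder arrays. No draw simulated that sharing, so independent lists are not the no-change value for them.

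The share of feeder signal in iPSC on feeder cells was measured to gauge how many feeder transcripts came along. Over 70 feeder-specific probes, 57 of them with a gene symbol, the on-feeder arrays read 5.12%, 3.54% and 5.38% (mean 4.68% ± 0.999, SD, n = 3). Feeder-free arrays, each read against the mean of the others, gave -0.0297% ± 0.214 (SD, n = 3). The probes were chosen as undetected on every feeder-free array, so this low reading was built in. The permutation test that follows uses it and is no independent control. The exact permutation test, two-sided, gave p = 0.1, the smallest that 3 against 3 arrays allow. Rebuilt mixtures with a true share of 8% read 5.6% ± 0.737 (SD, n = 3), over a range (4.84% to 6.31%) that overlaps that of the on-feeder arrays. On the 2 probes of the fibroblast list alone the on-feeder arrays read 8.37% and the mixtures 6.56%. The share was not uniform: it was 35.2% for the mesothelin gene Msln, 30% for Ccl9, 24.1% for Ltbp3 and 18.5% for Slit2, but 1.88% for Polr1b and 0.169% for Npy1r. As read, without scaling by the mixtures, 20 probes lay over 8%, 5 over 16% and 15 under 2%. Probes named here were chosen after their values were seen.

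**Figure D3:**
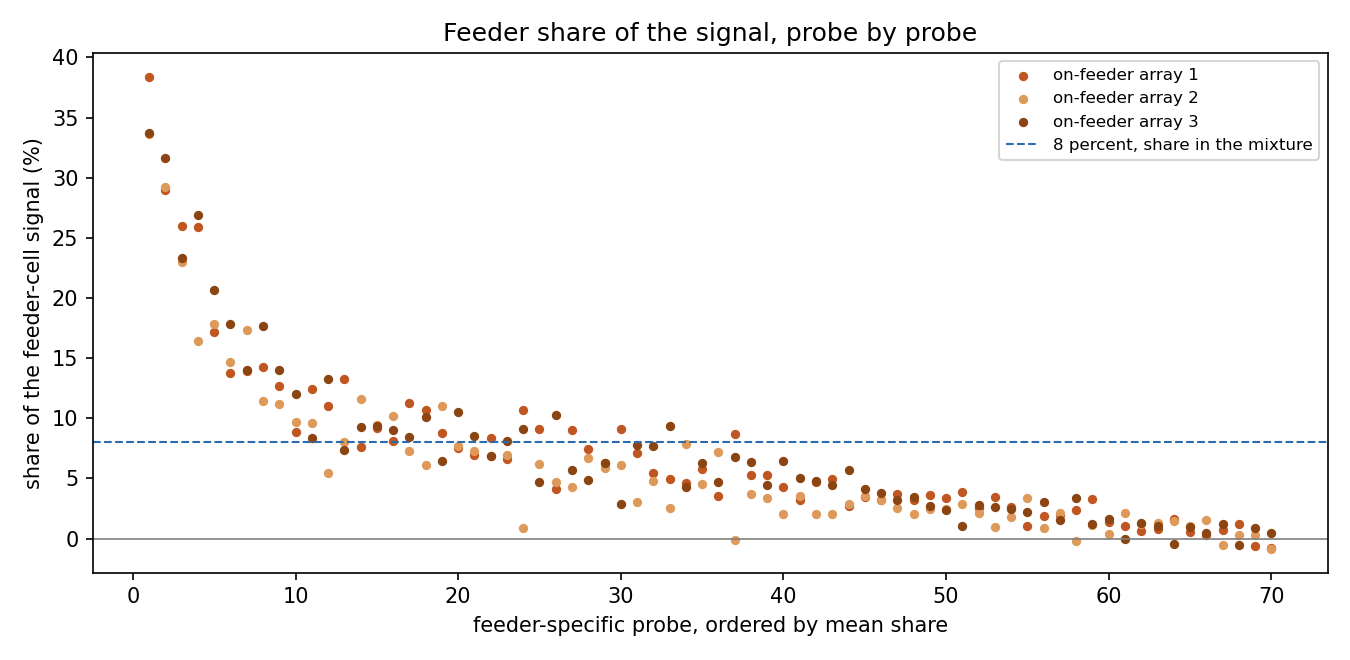
Share of the feeder-cell signal on each on-feeder array, in percent, for 70 feeder-specific probes ordered by their mean, with the 8% of the mixtures as a dashed line. Most probes lie under 8%, while Msln, the highest, averages 35.2%. The line marks the true share of the mixtures, which on these probes read 5.6% on average, so it is not on the scale of the points.

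Against the in silico mixture, which allows for feeder cells carried over at 8%, several chemokines stayed higher while the list median fell from 0.45 to 0.20. The mixtures hold the same feeder mean, so SEs and p-values here leave out the spread between feeder arrays and are too small for feeder genes. Cxcl1 was 12.2-fold above the mixture (log2 fold change 3.60, SE 0.10, adjusted p = 1.95e-08; n = 3 and 3), Ccl2 at least 4.56-fold (2.40, SE 0.10, adjusted p = 1.37e-06) and Ppbp at least 4.97-fold (2.41, SE 0.12). Ccl7 (1.83) and Ccl9 (1.54) were also above it, whereas Cxcl12 (-0.97, feeder share 2.26%) and Cxcl16 (-0.80) were below. Lif remained higher, at 0.77 (SE 0.09, adjusted p = 0.000557). Pou5f1 (-0.04, SE 0.12, adjusted p = 0.835), Nanog (0.31, adjusted p = 0.201) and Sox2 (-0.20, adjusted p = 0.387) did not pass the test. Klf4 was lower at -0.82 (SE 0.14, adjusted p = 0.00612), a call that ended at -0.34 when the mean over its probes was taken.

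Some feeder genes lay above the mixture and others below it. S100a4 (2.16, SE 0.11), Ecm1 (2.09), Tnc (1.96), the small proteoglycan gene Dcn (1.90), Igfbp7 (1.89), Cd44 (1.75), Mmp3 (1.44) and Thbs2 (1.34) were above it, each with adjusted p of 4.11e-05 or less; so was Ifi27 (1.96). Mmp13, not detected in feeder cells or feeder-free iPSC, was at least 3.27-fold above the mixture. Feeder shares were 74.7% for Dcn, 140% for Igfbp7, 38.7% for Mmp3 and 29% for Thbs2. Ptn, the gene most enriched in feeder cells, was below the mixture at -1.87 (SE 0.12, adjusted p = 7.55e-06) with a feeder share of 1.67%, as were the transcription factor gene Osr2 (-1.34, 1.69%) and Polr1b (-1.20). In the fibroblast and extracellular matrix list 13 of 28 were higher and 3 lower (15 and 4 adjusted over the list alone), and 12 did not pass the test (median 0.31, adjusted p = 2.04e-06, adjusted p = 0.332 with an estimated correlation); those lower were the crosslinker genes Lox (-0.66), Loxl1 (-0.51) and Loxl2 (-0.60), the last a gene higher in feeder-free iPSC than in feeder cells. The chemokine list had 6 of 13 higher and 2 lower (6 and 3 adjusted over the list alone; adjusted p = 0.00831, adjusted p = 0.332 with an estimated correlation, adjusted p = 0.0754 against a mixture with 16% feeder signal, adjusted p = 0.133 without the filter on dim probes).

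The primitive endoderm and BMP-SMAD lists were lower than in the mixture, while the mesoderm list was no longer called though its median changed little (-0.21 to -0.19). In the primitive endoderm list 6 of 15 were lower and 1 higher (8 and 1 adjusted over the list alone; adjusted p = 0.00432, adjusted p = 0.332 with an estimated correlation), with Gata4 at -1.09 (SE 0.12, adjusted p = 0.000528), Fst at -0.84, Foxa2 at -0.61 and Col4a1 at -0.53. BMP-SMAD targets had 3 of 7 lower and 0 higher, the same adjusted over the list alone (adjusted p = 0.0109, adjusted p = 0.332 with an estimated correlation), including Bmp4 at -0.67 and Hey1 at -0.77. Again Id1, Id2, Id3 and Id4 did not pass the test. The falls of Nptx2 (-1.65), Gkn1 (-1.59), Gkn2 (-1.40), Pga5 (-1.25), Nxf7 (-1.23), Tcf23 (-1.22) and Cdh5 (-1.15) were close to those against feeder-free iPSC. None of these genes was detected on a feeder array, so an 8% mixture could hardly move their reference. Their closeness was therefore built in and is no further support. Fbxw5 was at -1.46 against the mixture with a wide SE of 0.39 (adjusted p = 0.0417) and at -0.79 against feeder-free iPSC (adjusted p = 0.611). Among pluripotency regulators Zfp57 (-0.82) was lower and Gbx2 (0.86) higher.

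The other 19 lists were not called against the mixture. Mesoderm and primitive streak had 0 of 8 higher and 4 lower (the same over the list alone; adjusted p = 0.0798; Hand1 -0.81), and naive pluripotency and LIF-responsive factors 1 of 16 and 3 (the same; adjusted p = 0.098). Counts of members higher and lower were 1 and 0 for core pluripotency (adjusted p = 0.765), 4 and 0 for JAK-STAT3 targets (adjusted p = 0.396; Ier3 0.87), 4 and 0 for actin cytoskeleton (5 and 1 over the list alone; adjusted p = 0.223; Cav1 1.88, Ankrd1 1.78, Anxa1 1.22) and 4 and 2 for FGF-ERK feedback (5 and 2 over the list alone; adjusted p = 0.395; Dusp5 0.66). They were 1 and 1 for WNT targets (2 and 2 over the list alone; adjusted p = 0.972; Axin2 -0.58), 4 and 2 for interferon response (5 and 4; adjusted p = 0.396), 3 and 1 for unfolded protein stress (adjusted p = 0.387; Chac1 0.64), 1 and 1 for oxidative stress (2 and 1; adjusted p = 0.765; Txnip 0.77), and 2 and 0 for p53 targets (2 and 2; adjusted p = 0.987; Fas 0.63). For G2/M genes they were 1 and 0 (0 and 0 over the list alone; adjusted p = 0.0798), for glycolysis 3 and 1 (4 and 2; adjusted p = 0.722), for cholesterol synthesis 0 and 0 (adjusted p = 0.396), for epiblast priming 0 and 1 (1 and 3; adjusted p = 0.223) and for germline 0 and 0 (adjusted p = 0.395). Trophoblast had 1 and 1 (adjusted p = 0.924), hematopoietic and endothelial cells 0 and 1 (1 and 2 over the list alone; adjusted p = 0.765) and housekeeping 1 and 0 (1 and 1; adjusted p = 0.924). None of the 4 calls held with an estimated correlation or against a mixture with 16% feeder signal (adjusted p from 0.0683 to 0.581), fry called 7 lists, and the median, mean and test differed in sign for actin cytoskeleton, trophoblast, p53 targets, hematopoietic cells and housekeeping.

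Against the mixture 1085 genes (10.8%) differed, 559 higher and 526 lower, of which 69 and 24 by at least 2-fold, and 2896 had an unadjusted p under the threshold. The on-feeder arrays and the mixtures did not overlap for 3398 genes. Chance gives 10% for independent columns, but the mixtures share the feeder mean, so that value does not hold for feeder genes. Of the genes above feeder-free iPSC 502 (50.6%) were also above the mixture, and of those below 434 (52%) were also below it. Of the 526 genes below the mixture 184 were higher in feeder cells than in feeder-free iPSC, as were 330 of the 559 above it. Among all genes tested, 4124 of 10058 were higher in feeder cells, so the genes below the mixture held a smaller share of them. Single columns moved the count to 559 without on-feeder replicate 1, 541 without on-feeder replicate 3, 396 without mixture 2 and 464 without mixture 3, and a mixture with 16% feeder signal gave 1731.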

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

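The tests of feeder RNA carried over, of background correction and normalization, of the share that dilution needs, of dilution in Fst and Serpinh1, and of the share of endoderm genes called lower were chosen only after the results they concern were seen; the other splits of the arrays and the first test of dilution were set out beforehand.

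The deposited feeder-free columns, which no comparison uses, carried feeder signal. The first and second feeder-free columns held 9% feeder signal and the third 8%. Recovered single feeder-free arrays read -0.0297% on feeder-specific probes, a low reading built in because those probes were chosen as undetected on these arrays. Probes without a single gene symbol also changed: 409 of 3992 differed between iPSC on feeder cells and feeder-free iPSC, 245 higher and 164 lower.

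The first pattern is that feeder-specific probes gave unequal shares in iPSC on feeder cells, from -0.394% to 35.2%. The SD between probes was 6.54 percentage points or more on each on-feeder array and at most 1.41 in 6 control mixtures that hold a common share of 8%, and with a wider set of 207 probes the lowest was still 3.19 times the highest control; yet the controls hold only array noise, and feeder cells may vary between cultures, so a common share stays open. Background correction and normalization are argued against, as mixtures with a true common share went through the same steps and that ratio was 2.03 or more with median scaling and without background correction in both probe sets. An earlier test, the SD between over that within probes, gave 3.51 with 70 probes and 1.91 with 207, had no control, and was replaced after its values were seen. A change of feeder or iPSC transcripts in co-culture, or carry-over of some feeder cells more than others, may explain the spread; neither was tested.

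The second pattern is that Ccl2, Ccl7, Ccl9, Cxcl1 and Cx3cl1 lay above the mixture. RNA carried over from feeder cells like those on the feeder arrays is argued against as the whole cause for Ccl2 and Cxcl1, whose implied share was 150% or more on each array, above those cells themselves, while a feeder layer that differed from them was not tested; for Ccl7, Ccl9 and Cx3cl1 (18.5% or more) it stays open, since genes above an 8% mixture have a high implied share by choice and these may be carried over more than other feeder RNA. Background and normalization are argued against, as all 5 were above the mixture under each of 3 other treatments, although the median log2 fold change of 1.83 fell to 1.31 without background correction. Cxcl12 had an implied share of 2.26% (1.46% to 2.96% by array), under the upper bound of its test, the highest on-feeder share. It also lay below the share of every on-feeder array (3.54% to 5.38%). The test asked only whether Cxcl12 was too high, so it cannot tell whether carry-over at a common share explains this gene. Il11 (16.4%) was set aside after its values were seen. That iPSC or feeder cells express these chemokines more in co-culture is a hypothesis that stays open and was not tested, since no array separates the cells.

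The third pattern is the fall of primitive endoderm genes. Among members that feeder cells express no less, Hnf4a did not pass the limma test (-0.30, adjusted p = 0.219) and Pdgfra rose on 1 of 2 probes. Dilution by feeder RNA is argued against only for the others, Fst and Serpinh1. They were picked after their values were seen because they were called lower (median -0.62), and they were also below the mixture, so dilution cannot be their whole cause. For the 11 members lower in feeder cells (median -0.47, past the -0.25 of a 16% share; 6 of 1000 draws of as many such genes were as low) it stays open: dilution would need a share of 17.2% to 34.3% by array where the arrays show at most 8.89% after scaling, just short of the bound of 2 times that share (17.8%), and members of a lineage may move together, so draws of single genes do not settle it. The bound set beforehand, the 10th percentile of single genes (-0.59), was a poor one for a median and decides nothing. Against a mixture with 16% feeder signal the median of the 11 was -0.20 (-0.33 to -0.02 by array) where it was -0.32 with 8% (-0.46 to -0.14), and the list call ended (adjusted p = 0.0754 by camera) as the fold shrank. Even so, 6 list members were still called lower there and 1 higher, the same counts as with 8%. Fewer endoderm-like cells in the cultures might lower such genes together and stay open, with 53.3% of the list called lower and Pdgfra higher on 1 of 2 probes, and an effect of feeder cells on these genes was not tested.

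The 6 arrays of each comparison part into 3 and 3 in 10 ways, the real one included, too few for a share under 0.05. The real split called 1827 genes and 7 lists on feeder against feeder-free, and it alone (1 of 10) reached that many; the highest of the others were 0 genes and 3 lists. Against the mixture the real split called 1085 genes and 4 lists, and the highest of the others again 0 and 3.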

How the results depend on the processing

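The mixtures built from a single feeder array, and the alternatives of the lists other than the estimated correlation and the replicate block, were chosen only after the data were seen. Values of the authors' normalized table were not run as an alternative, because its iPSC columns did not match by probe. Between feeder-free iPSC and feeder cells the count stayed between 7062 and 9204; leaving out arrays gave 7653 to 8001. Rpl13a alone among named genes reversed, from 0.62 to -0.059 with median scaling; the cause was not tested. On feeder against feeder-free the count ranged from 1541 to 2130, and from 1137 to 2154 with an array left out; against the mixture it ranged from 757 to 1499 under the other processing choices, was 1731 with 16% feeder signal, and 396 to 1524 with a column left out, where fewer arrays enter the fit. With a replicate block the counts were 1583 and 795, and the lists 7 and 4; paired deviations of same-numbered arrays correlated at 0.0241, 0.162 and -0.198 (differently numbered ones from -0.355 to 0.341). An estimated correlation left 0, 1 and 0 of the 10, 7 and 4 lists called, and mixtures with 4%, the measured and 16% feeder signal gave 7, 7 and 0 lists; other alternatives stayed within 3 to 5 there and 6 to 7 against feeder-free iPSC. The feeder share of 4.68% became 3.64% on 4 probes at a fold minimum of 32 and 8.37% on the 2 probes of the fibroblast list; the cause was not tested, and fewer probes were read. Without background correction it was 5.66%, with median scaling 3.7%, and with an array left out 4.4% to 5.32%. Named genes kept direction and side of the threshold under every alternative in 141 of 146 cases for feeder-free iPSC against feeder cells, in 72 of 102 for on feeder against feeder-free and in 48 of 84 against the mixture; Ccl2, Cxcl1, Gata4 and Lif were among them in the last 2. Signal over background limits folds of genes undetected in a group, which are lower bounds.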

Other observations

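No test in this part was planned, and its values carry no explanation. The feeder arrays differed in iPSC-specific signal. Over the 100 probes with the highest ratio of feeder-free to feeder signal, 93 were brighter on feeder array 2 than on feeder array 1, by a median of 11.1 signal units, where undetected probes differed by 2.2. The median difference was 0.617% of the feeder-free level, and 17 of these probes were detected on feeder array 1 against 37 on feeder array 2. Folds of iPSC genes over feeder cells, such as that of Dnmt3l, depend on this small signal.

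Several genes outside the naming rule, singled out after their values were seen, stood above both feeder-free iPSC and feeder cells. They also stood above the mixture, but a gene above both of its parts does so largely by construction. The adhesion receptor gene Selp rose at least 1.73-fold over feeder-free iPSC and at least 1.24-fold over feeder cells, and Ptpn22 at least 1.69-fold and 1.21-fold. Il33, which encodes an alarmin cytokine, rose by 0.86 and 0.75 on the log2 scale, and the Hippo-pathway coactivator gene Wwtr1 by 1.39 and 1.52. Mmp10 rose by 1.34 and Serpinb2 at least 2.21-fold over feeder-free iPSC.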
